A study of Pseudomonas aeruginosa with 4 samples.

How the data were processed

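RNA of 4 Pseudomonas aeruginosa PAO1 cultures was sequenced, 1 for each combination of oxythiamine (0 or 3 mM) and time (30 or 180 min). Per the labels' protocols, RNA was column-purified, ribosomal RNA was depleted and stranded libraries were prepared. The submitters' processing notes name Bowtie2 and edgeR without versions. The genome build, the annotation and the read counter are not given in the sources used here.

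One deposited table covers the series. Per the file headers it holds, for each library, a read count per gene and a normalized value, and 1 column of edgeR p-values. The counts are whole numbers as the authors deposited them, with library totals of 3873645, 4876699, 5356443 and 2076126. The authors' normalized signal is the count multiplied by 1 factor per library (1.28, 1.02, 0.661 and 1.23 for control 30 min, oxythiamine 30 min, control 180 min and oxythiamine 180 min), checked over the genes of the table. The deposited p-value column names no comparison. Its ranks were compared with those of an edgeR exact test at an assumed biological coefficient of variation of 0.4, and Spearman's rho was 1.000 for the pair of libraries at 180 min, 0.121 for the pair at 30 min, 0.125 for the control over time and 0.326 for oxythiamine over time. The treated columns abbreviate the compound otherwise than the sample titles do, and were matched to the samples by their time and by not being controls.

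The table lists 5571 genes by locus tag. All 5571 matched the RefSeq table of assembly ASM676v1, in which all are protein coding and 1753 have a symbol of their own. That table was used for names and for the order of neighbouring genes, and no coordinates are given because no source names the build of the counts. Genes without a symbol are called by locus tag. Reads of near-identical copies, such as the 2 phenazine operons, can be exchanged in counting, and values of such genes are uncertain. No ribosomal or transfer RNA is in the table, so library sizes are sums over protein-coding genes.

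Counts were scaled with the trimmed mean of M-values in edgeR 4.0.16 under R 4.3.3, with factors of 0.808, 0.798, 1.11 and 1.40 in the order of the totals above. Genes with a mean of at least 20 reads over the 4 libraries were kept, 5282 in number. Log2 ratios were taken from scaled CPM with a prior count of 2, and genes were counted as apart at 2-fold, or at 4-fold for the difference between the times. Printed folds are plain ratios of scaled reads without the prior count, with exact conditional binomial (Clopper-Pearson) 95% intervals on the 2 counts. Count intervals are exact Poisson. A gene with no read could have up to 3 counts, which is 0.959, 0.772, 0.505 and 1.04 scaled CPM in the 4 libraries. With 1 library per group no p-value was computed for a pair of libraries, and neither sizes nor intervals include variation between cultures. Counts drawn 100 times with the 2 libraries of a pair at the same underlying level gave the number of 2-fold genes that counting error makes.

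The 26 gene lists were fixed before the data were examined. Their measured members ranged from 4 to 53 genes. The median of each was placed among the medians of 10000 random lists of the same size, matched on expression in 10 bins, which describes these libraries and is not a test of the conditions. The same procedure was applied to the eggNOG function categories that the deposited table gives for 4747 genes. Runs of at least 4 consecutive measured genes apart in the same direction were set beside 1000 shuffles of the ratios. The additive model of time and treatment was fitted to all 4 libraries with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and with DESeq2 1.42.0 as an alternative. The remaining work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

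Genes named in the text follow a rule fixed before the data were examined: at each time the 8 largest ratios in each direction among genes with a symbol, the 3 largest whatever the name, all members of the thiamine biosynthesis and thiamine pyrophosphate enzyme lists, and up to 3 members of each other list with the largest ratio. For the difference between times and the changes with time the rule takes the 5 largest in each direction with a symbol, and for the additive model the 5 largest called genes in each direction. Other genes, such as members of runs of neighbours, PA2146, PA1420 and PA5391, were named after their values were seen.

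The ratios and the additive test were tried on simulated counts drawn from the means and depths of these libraries, with 200 changed genes. At 30 min 98.5% of 4-fold changes and 53.7% of 2-fold changes came out past 2-fold, and at 180 min 100% and 49.3%. The additive edgeR test recovered 95.5% of 2-fold changes at a dispersion of 0.01, with 6 false calls, but 1.49%, 37.3% and 89.4% of 2-fold, 4-fold and 8-fold changes at the dispersion of 0.125 fitted here. All simulated genes had the same dispersion, which measured genes need not have. These shares are therefore not the power of the test on the measured genes. The list procedure was tried instead on independent normal values, the same for both times, with only the expression bins differing. Among 100 unshifted lists of 15 genes 6 stood apart with the bins of 30 min and 8 with those of 180 min. All 100 lists shifted by 1 on the log2 scale stood apart. These values had neither the spread of the measured ratios nor operons, so 6 and 8 are not error rates for the measured lists.

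The alternatives were total-count scaling, median-of-ratios scaling, the authors' normalized values, prior counts of 0.5 and 5, no filter, a mean of at least 100 reads and, for the additive model, DESeq2, median-of-ratios scaling, no filter and no time term. Chosen after seeing the data were libraries thinned to the smallest total and the condition that the counting interval leaves out 1.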

Results

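Transcripts of Pseudomonas aeruginosa PAO1 were measured in cultures grown in glucose minimal medium, without or with 3 mM oxythiamine. Oxythiamine is a structural analog of thiamine, the vitamin whose pyrophosphate ester is the cofactor of pyruvate dehydrogenase, transketolase, acetolactate synthase and related enzymes. RNA was collected at 30 and at 180 min from control and treated cultures, which gave 4 groups with 1 library each. The libraries held 3873645 gene-assigned reads in the control at 30 min, 4876699 with oxythiamine at 30 min, 5356443 in the control at 180 min and 2076126 with oxythiamine at 180 min. The gene oprF, which encodes the major outer membrane porin, took the largest share of reads in each library, from 1.37% to 2.60%. With 1 library per group there is no replicate check on any difference between a treated and a control library. Ranges in parentheses after a fold are 95% exact binomial counting intervals, which cover counting error only and leave out the variation between cultures. Because reads from amplified libraries are not independent molecules, even the counting part may be wider than these intervals.

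At 30 min the question was which transcripts differed early in the presence of the analog. The pyruvate dehydrogenase genes aceF and aceE had the largest ratios. aceF, which encodes the acetyltransferase subunit, was 9.48-fold (8.97 to 10.03) higher in the treated library, and aceE, which encodes the thiamine pyrophosphate-binding subunit, was 7.43-fold (7.23 to 7.64) higher. aceE had 5734 reads in the control and 52978 with oxythiamine. PA5435 and PA5436, listed for the pyruvate carboxylase subunits, were 2.32-fold (2.14 to 2.52) and 1.71-fold (1.57 to 1.86) higher. In the other direction, 5 of the 8 largest ratios among genes with a symbol belonged to the liu cluster of leucine catabolism. liuA was 3.20-fold (2.74 to 3.74) lower, liuC 2.74-fold (1.97 to 3.85), liuB 2.44-fold (1.87 to 3.22) and liuD 2.29-fold (1.81 to 2.90) lower, and their regulator liuR was 2.83-fold (2.23 to 3.62) lower. PA3598 was 7.04-fold (5.24 to 9.61) lower and its neighbour PA3597 was 3.28-fold (2.27 to 4.81) lower. The cyanide-insensitive oxidase gene cioB was 2.30-fold (1.75 to 3.05) lower and the efflux porin gene oprN was 2.62-fold (1.48 to 4.78) lower.

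Of 5282 genes with a mean of at least 20 reads, 25 were at least 2-fold higher and 40 at least 2-fold lower with oxythiamine at 30 min, together 1.23% of the genes. Counts drawn with no difference between the 2 libraries gave a mean of 29.5 such genes, 45.4% of the number observed. With the added condition that the counting interval leaves out 1, there were 18 higher and 36 lower genes, 54 in all, against a mean of 17.2 in the drawn counts. Several genes among the largest ratios rested on few reads. PA1237 had 3 reads in the control and 21 with oxythiamine, a ratio of 5.63 (1.68 to 29.5). exaB, an ethanol oxidation gene, had 2 and 8 reads, a ratio of 3.22 (0.642 to 31.1), and napE had 9 and 4 reads, with a ratio 2.80-fold lower (0.781 to 12.4). The intervals of pykF (1.37 to 8.72), soxR (1.30 to 3.34), fabH2 (1.24 to 3.31) and ercS' (1.05 to 4.05) left out 1, and that of algK (0.962 to 5.24) did not.

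The 26 gene lists fixed before the data were examined were compared with random lists of the same size and expression. In this paragraph and in those on 180 min, a list is said to stand apart when its median lay outside the central 95% of the random medians. About 1 list in 20 would do so by chance if its members were independent. Genes of an operon are transcribed together, so members of a list are not independent. Lists of operon genes can therefore stand apart by chance more often than that. At 30 min 6 lists stood above and 5 below the random lists, nearly all with small medians. The 21 enzymes using thiamine pyrophosphate and their complex partners had a median log2 ratio of 0.20, above 99.9% of random lists, with 2 members at least 2-fold higher, aceE and aceF. The TCA cycle list had a median of 0.20 over 17 genes, with sdhC 1.34-fold (1.29 to 1.40) and icd 1.28-fold (1.22 to 1.34) higher and mqoB 1.30-fold (1.23 to 1.38) lower. Quorum sensing genes had a median of 0.27, with lasI 1.74-fold (1.59 to 1.91) higher. Heat shock genes had a median of 0.21, with groEL 1.34-fold (1.28 to 1.41) higher. NADH dehydrogenase I genes had a median of 0.13, with nuoA 1.27-fold (1.17 to 1.39) higher. Glucose catabolism genes had a median of 0.09, with pgl 1.74-fold (1.59 to 1.91) and gltR 1.72-fold (1.54 to 1.94) higher and none of the 21 past 2-fold.

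Below the random lists at 30 min stood branched-chain amino acid catabolism, with a median of -0.38 and 5 of 12 members at least 2-fold lower. Its median was -0.05, and no longer apart, in libraries thinned to the same total of reads, an alternative chosen after seeing the data. The arginine deiminase list had a median of -0.36, with the antiporter gene arcD 1.59-fold (1.56 to 1.63) lower. The type III secretion list had a median of -0.22, denitrification -0.20 and ATP synthase -0.14, and none of their 23, 20 and 9 members reached 2-fold. The denitrification list was also no longer apart in the thinned libraries, at -0.16. Thiamine biosynthesis genes had a median of -0.04, within the random range. Among its 7 members thiC, which makes the pyrimidine part of thiamine, was 1.73-fold (1.61 to 1.85) lower, and thiD was 1.15-fold (0.966 to 1.38) and thiG 1.09-fold (0.990 to 1.21) higher. thiE, thiL, thiI and PA0380 were between 1.02-fold and 1.10-fold lower.

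**Figure D1:**
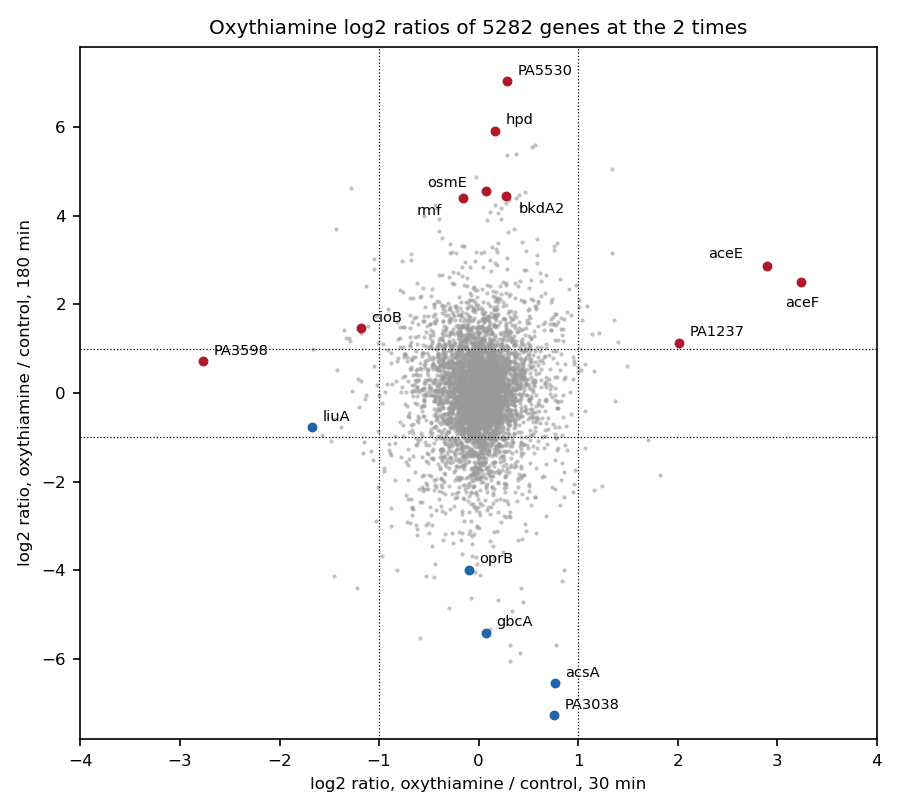
Each point is 1 of 5282 genes, with the log2 ratio of oxythiamine to control at 30 min on the x axis and at 180 min on the y axis, and dotted lines at 2-fold. Coloured, labelled points are genes named in the text, red where higher and blue where lower at 180 min, and aceE and aceF lie far from the other genes at the upper right, with log2 ratios of 2.89 and 3.24 at 30 min and 2.86 and 2.51 at 180 min.

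At 180 min the treated and control libraries were much farther apart. The branched-chain keto acid dehydrogenase genes were among the largest ratios, with bkdA1 17.2-fold (15.2 to 19.4), bkdA2 22.1-fold (18.6 to 26.5), bkdB 19.9-fold (16.5 to 24.1) and lpdV 21.4-fold (18.1 to 25.4) higher with oxythiamine. From 30 to 180 min bkdA1 fell in the control from 268 to 50.7 scaled CPM, and it rose with oxythiamine from 290 to 871. hpd, a dioxygenase gene of tyrosine breakdown, was 61.2-fold (53.0 to 71.1) higher. Also among the 8 largest ratios with a symbol were the osmotically inducible protein genes osmE at 23.7-fold (21.1 to 26.7) and osmC at 21.1-fold (17.0 to 26.7), the ribosome modulation factor gene rmf at 21.01-fold (19.7 to 22.4) and the outer membrane protein gene lptF at 19.1-fold (17.8 to 20.5). The largest ratio of all was that of PA5530 at 134-fold (114 to 158), and PA5030 was 49.99-fold (40.4 to 62.5) higher. In the other direction PA3038 was 157-fold (120 to 209) lower, and acsA, which encodes acetyl-CoA synthetase, was 93.9-fold (77.6 to 115) lower, with 20207 reads in the control and 105 with oxythiamine.

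The largest ratios in this direction also included gbcA, a glycine betaine breakdown gene, at 43.6-fold (32.5 to 59.9), the dimethylglycine breakdown gene dgcA at 21.4-fold (17.4 to 26.5) and the sarcosine oxidase genes soxD at 21.6-fold (11.3 to 47.6) and soxB at 18.1-fold (14.1 to 23.7). PA5392 was 68.2-fold (48.5 to 99.1) lower. The guanidinobutyrase gene gbuA was 17.8-fold (14.3 to 22.4) lower, the peptide porin gene opdP 17.3-fold (14.4 to 20.8) and the glucose porin gene oprB 15.8-fold (15.04 to 16.5). Several of these ratios came with a rise in the control from 30 to 180 min and not with a fall in the treated culture. gbcA went from 9.27 to 677 scaled CPM in the control and from 9.77 to 15.5 with oxythiamine. For PA5392 these were 3.84 to 776 and 4.89 to 11.4, and for opdP 23.7 to 733 and 23.9 to 42.5. acsA rose from 480 to 3404 in the control but fell from 816 to 36.2 with oxythiamine. In all, 727 genes were at least 2-fold higher and 724 at least 2-fold lower, 27.5% of the 5282. Counts drawn with no difference gave a mean of 3.48 such genes. The balance of the directions depended on the scaling and on the filter. With total-count scaling, which moved the median log2 ratio of all genes from 0.03 to 0.36, 1159 genes were higher and 473 lower, so that 71.0% of the genes apart were higher instead of 50.1%. With a mean of at least 100 reads 318 of 3579 genes were higher and 503 lower, so that 38.7% of the genes apart were higher.

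Enzymes using thiamine pyrophosphate stood above the random lists at 180 min, with a median log2 ratio of 1.13, 12 of 21 members at least 2-fold higher and 2 at least 2-fold lower. aceE was 7.24-fold (7.09 to 7.39) and aceF 5.71-fold (5.51 to 5.91) higher, and the pyruvate oxidase gene poxB was 10.7-fold (8.62 to 13.4) higher. The other members past 2-fold, besides the 4 bkd and lpdV genes, were mdlC at 4.60-fold (3.08 to 6.97), PA3416 at 6.70-fold (4.69 to 9.75), PA3417 at 3.53-fold (2.58 to 4.87), PA4150 at 2.24-fold (1.58 to 3.18) and PA4152 at 2.17-fold (1.33 to 3.54). PA3416 and PA3417 were listed for pyruvate dehydrogenase subunits, and PA4150 and PA4152 for acetoin dehydrogenase subunits. The acetolactate synthase genes ilvH and ilvI, which serve branched-chain amino acid synthesis, were 5.62-fold (4.90 to 6.48) and 2.95-fold (2.75 to 3.17) lower. The 2-oxoglutarate dehydrogenase genes sucA and sucB were 1.02-fold (0.993 to 1.05) and 1.08-fold (1.04 to 1.13) higher, and the transketolase gene tktA was 1.64-fold (1.53 to 1.76) lower. gcl was 1.34-fold (0.972 to 1.84) and acoB 1.47-fold (1.01 to 2.14) higher, and lpdG and dxs were 1.06-fold (1.02 to 1.10) and 1.05-fold (0.967 to 1.13) lower. The directions of sucA and sucB turned with the authors' scaling, and those of lpdG and dxs with total-count scaling. With the authors' scaling PA4150 and PA4152 were under 2-fold, which left 10 members at least 2-fold higher.

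All 10 measured genes for the siderophore pyochelin were at least 2-fold higher at 180 min, with a median of 1.58 and with pchR at 4.56-fold (2.71 to 7.92), pchC at 4.44-fold (2.84 to 7.09) and pchD at 3.79-fold (2.78 to 5.19), but 9 of the 10 with median-of-ratios or the authors' scaling. The pyoverdine list had a median of 0.94, with 6 of 15 members at least 2-fold higher and 1 lower, and with pvdH at 5.02-fold (2.93 to 8.91) and pvdL at 4.36-fold (3.68 to 5.17). Phosphate starvation genes had a median of 0.77, with 4 of 12 at least 2-fold higher, among them the alkaline phosphatase gene phoA at 3.62-fold (2.27 to 5.87) and the phosphate-binding protein gene pstS at 2.46-fold (2.13 to 2.85). Type III secretion genes had a median of 0.68, with 7 of 23 at least 2-fold higher, among them the activator gene exsA at 2.53-fold (1.997 to 3.20) and pcrV at 3.18-fold (2.36 to 4.32). These 3 lists and the pyochelin list stood above the random lists under each of the 4 scalings, but with total-count scaling the members at least 2-fold higher were 10 for pyoverdine, 8 for phosphate starvation and 12 for type III secretion.

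At 180 min 6 lists stood below the random lists. Of 53 ribosomal protein genes 40 were at least 2-fold lower and none higher, with a median of -1.46, below all 10000 random lists. rplJ was 6.78-fold (6.33 to 7.28), rplL 5.95-fold (5.52 to 6.42) and rpsF 4.79-fold (4.38 to 5.25) lower. Glucose and gluconate catabolism had a median of -1.15, with 14 of 21 members at least 2-fold lower. Besides oprB, PA3189 and PA3188, listed for parts of the glucose transporter, were 12.3-fold (11.1 to 13.8) and 8.85-fold (8.02 to 9.80) lower. Heat shock genes had a median of -1.15, with 8 of 12 at least 2-fold lower and 1 higher, and with groEL 3.67-fold (3.55 to 3.80), groES 3.24-fold (2.84 to 3.70) and clpB 2.88-fold (2.65 to 3.13) lower. From 30 to 180 min groEL rose from 779 to 4840 scaled CPM in the control and from 1046 to 1319 with oxythiamine. Flagellar genes had a median of -0.95, with 12 of 24 at least 2-fold lower, among them flgB at 4.19-fold (3.54 to 4.98) and flgC at 4.13-fold (3.43 to 5.003). The arginine deiminase list had a median of -1.62, with arcD 6.70-fold (6.37 to 7.05) and arcA 4.34-fold (4.05 to 4.64) lower. Quorum sensing genes had a median of -0.42, with 6 of 24 at least 2-fold lower, among them the hydrogen cyanide synthesis genes hcnA at 10.4-fold (5.34 to 23.0), hcnB at 6.08-fold (4.58 to 8.23) and hcnC at 5.76-fold (4.49 to 7.51). All 6 stood below the random lists under each of the 4 scalings, but with total-count scaling there were 6 of 21 glucose genes lower and 1 higher, with a median of -0.82, 3 of 12 heat shock genes lower, with a median of -0.82, and 4 of 24 quorum sensing genes lower, with a median of -0.09. The authors' scaling gave 8 of 24 quorum sensing genes lower, with a median of -0.56.

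The other lists lay within the random range at 180 min. Branched-chain amino acid biosynthesis had a median of -0.84 with 5 of 11 members at least 2-fold lower, among them ilvC at 4.49-fold (4.24 to 4.77), and ATP synthase had a median of -1.04 with 5 of 9 lower, among them atpG at 2.49-fold (2.33 to 2.66). Alginate synthesis had a median of 1.13 with 9 of 11 members at least 2-fold higher, among them algK at 5.98-fold (3.71 to 9.94). Random lists of its expression were themselves mostly higher, with medians from -0.05 to 1.22. For the ribosomal protein list that range was -0.68 to -0.25, so counts of higher or lower members depend partly on expression. The exopolysaccharide list had a median of -0.02, with 7 pel genes at least 2-fold higher, among them pelB at 6.19-fold (4.84 to 7.99), and 12 members between the limits. Pyruvate overflow and acetate metabolism had a median of -0.48 with 2 members at least 2-fold higher and 6 lower, among them the acetate kinase gene ackA at 4.46-fold (3.997 to 4.99) lower. Denitrification had a median of 0.38 with 6 members higher and 4 lower, from nosF at 6.40-fold (3.59 to 12.04) higher to nirS at 7.55-fold (6.38 to 8.99) lower. Branched-chain amino acid catabolism had a median of 0.16 with 4 members higher and 3 lower. Multidrug efflux had a median of 0.48 with 4 of 15 higher, the pyocin cluster 0.39 with 2 of 35 higher, and the SOS response 0.38 with 2 of 8 higher. Phenazine synthesis had a median of 0.52 with 1 of 13 higher, but reads of its 2 nearly identical operons may be exchanged, so these values are uncertain. The TCA cycle list had a median of -0.32 with acnA 2.69-fold (2.57 to 2.82) higher and mqoB 3.29-fold (3.01 to 3.59) and aceA 2.18-fold (2.10 to 2.27) lower. NADH dehydrogenase I had a median of -0.33 and oxidative stress defence a median of -0.02, with no member past 2-fold. Thiamine biosynthesis had a median of 0.12, with thiC 2.07-fold (1.95 to 2.19), thiL 1.44-fold (1.19 to 1.75) and thiG 1.41-fold (1.26 to 1.58) higher and thiI 1.65-fold (1.35 to 2.02) lower, while thiD, thiE and PA0380 were less than 1.10-fold from the control. With total-count scaling the medians of the TCA cycle, NADH dehydrogenase I, exopolysaccharide and oxidative stress lists lay above 0, and with the authors' scaling that of thiamine biosynthesis lay below 0, with thiC under 2-fold. Total-count scaling left 0 of 9 ATP synthase genes at least 2-fold lower, with a median of -0.71, and put aceA under 2-fold, which left 1 TCA cycle gene lower, and it put 9 denitrification, 7 pyocin, 5 phenazine, 4 SOS and 2 oxidative stress genes at least 2-fold higher. The authors' scaling put 5 alginate, 2 efflux, 1 SOS and 0 pyocin and phenazine genes at least 2-fold higher, and 4 TCA cycle genes at least 2-fold lower where the main scaling had 2.

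**Figure D2:**
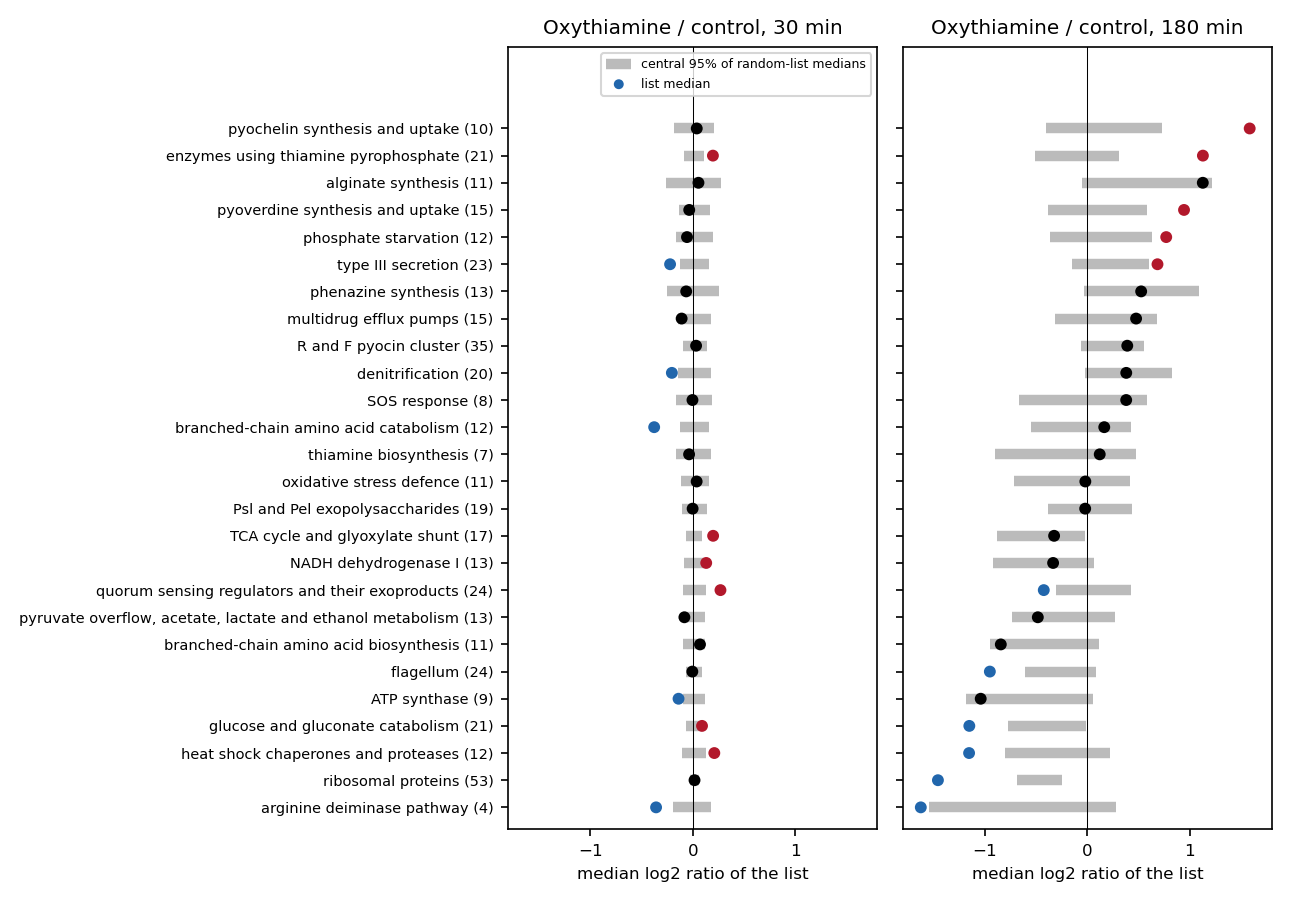
Dots are the median log2 ratio of oxythiamine to control for each of 26 gene lists, with the number of measured members in parentheses, at 30 min (left) and 180 min (right), and grey bars span the central 95% of medians of 10000 random lists of the same size and expression. Dots are red above and blue below that range, and medians reach from -0.38 to 0.27 at 30 min and from -1.62 to 1.58 at 180 min.

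The oxythiamine ratios at the 2 times were compared gene by gene, with no library shared between them. Across the 5282 genes, which are not independent replicates, Pearson's r was 0.0565 and Spearman's rho was 0.0439. At both times 13 genes were at least 2-fold higher, where independent lists would share 3.44, and 9 were at least 2-fold lower, where independent lists would share 5.48. The 13 higher genes included aceE, aceF, PA5435 and PA1237, and the 9 lower genes included liuR. In opposite directions were 5 genes higher at 30 and lower at 180 min and 14 lower at 30 and higher at 180 min. Since 727 genes were higher and 724 lower at 180 min, independent lists would share nearly as many in opposite directions. The opposite overlaps were thus also above those numbers, and the shared genes alone do not show agreement between the times. These counts depended on the prior count, the filter and the depth: the genes higher at both times numbered 7 with a prior count of 5, 24 with no filter and 3 with a mean of at least 100 reads, and those in opposite directions 3 and 8, 5 and 22, and 1 and 5, and in thinned libraries 11 and 16. The ratio differed between the times by at least 4-fold for 404 genes, 195 of them higher at 180 min and 209 lower. With total-count scaling these were 301 and 135. The largest differences among genes with a symbol were those of hpd, 5.75 on the log2 scale, pfpI at 4.68, rmf at 4.55, osmE at 4.48 and bkdA2 at 4.16, and in the other direction acsA at -7.30, gbcA at -5.47, soxD at -5.07, dgcA at -4.82 and opdP at -4.11. No test of these differences was possible.

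**Figure D3:**
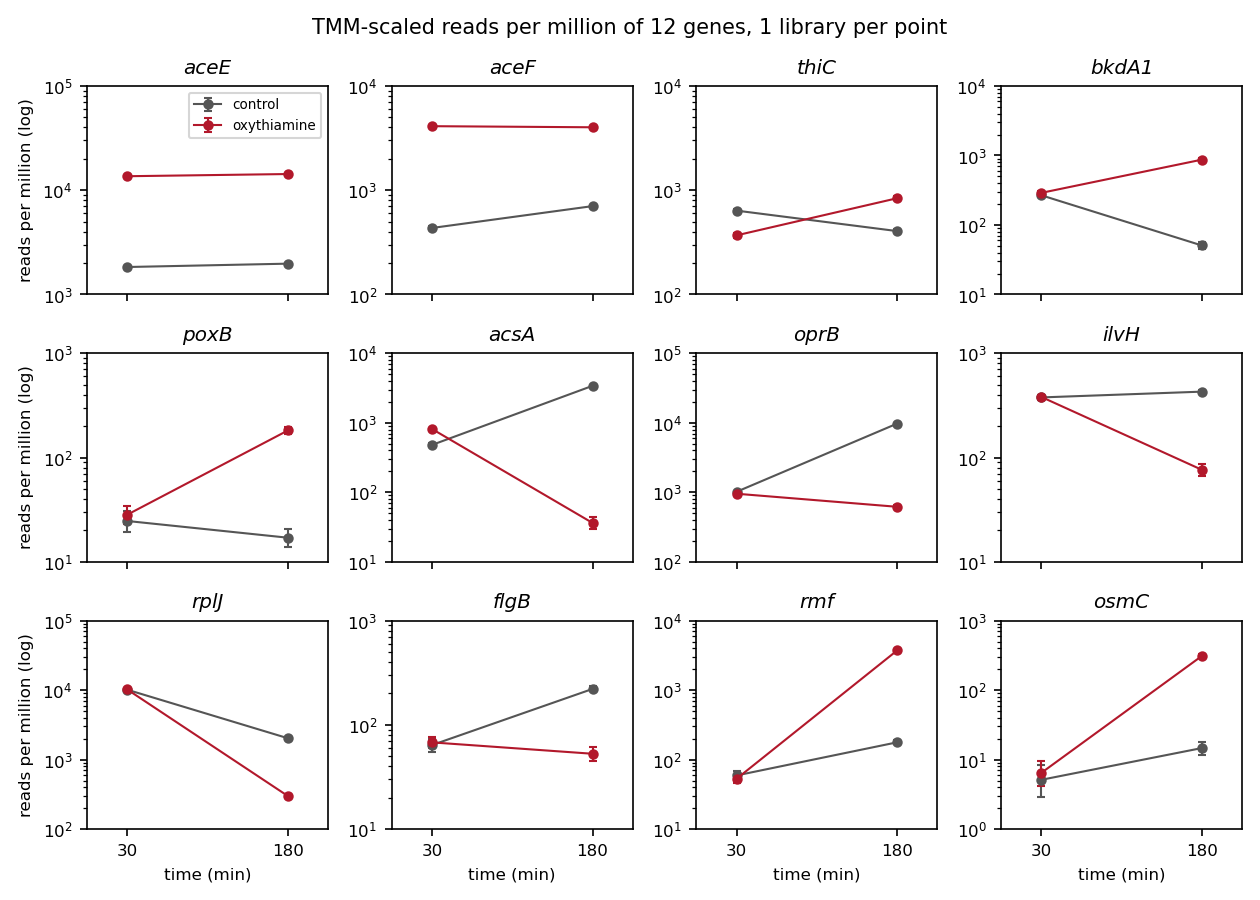
Scaled CPM (trimmed mean of M-values), on log axes, are shown for 12 genes at 30 and 180 min in control (grey) and oxythiamine (red), 1 library per point, with bars for exact 95% Poisson counting intervals. aceE and aceF were already apart at 30 min, with 434 against 4116 CPM for aceF, whereas bkdA1, poxB, oprB, ilvH, rplJ, flgB, rmf and osmC were close at 30 min and apart at 180 min.

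The change from 30 to 180 min in the untreated culture gives the background for the treated one. In the control 1004 genes were at least 2-fold higher and 779 at least 2-fold lower at 180 min. pra was 144-fold (116 to 181) higher, gbcA 73.0-fold (50.8 to 109), lipC 55.8-fold (31.1 to 112) and dgcA 52.3-fold (38.5 to 73.0) higher, and soxD had 2 reads at 30 min and 398 at 180 min, a ratio of 105 (28.8 to 869). The cytochrome bo oxidase genes cyoA, cyoE and cyoC were 24.2-fold (18.3 to 32.8), 17.4-fold (11.8 to 26.5) and 16.7-fold (11.5 to 24.8) lower, the glycerol phosphate dehydrogenase gene glpD 14.4-fold (13.1 to 15.98) and the proline catabolism gene putA 12.8-fold (11.8 to 13.8) lower. With oxythiamine 1227 genes were at least 2-fold higher and 967 at least 2-fold lower at 180 min. pfpI was 93.4-fold (57.3 to 164), rmf 70.4-fold (61.3 to 81.1), osmE 63.0-fold (50.2 to 80.1), osmC 48.2-fold (32.4 to 74.9) and lptF 30.4-fold (27.4 to 33.8) higher. The aspartase gene aspA was 39.2-fold (33.2 to 46.5) lower, and the translation genes rplJ, rpsF, rpsR and tsf were 34.1-fold (31.9 to 36.5), 31.7-fold (29.0 to 34.6), 31.5-fold (28.4 to 35.0) and 29.1-fold (26.5 to 31.9) lower. Across genes, the changes with time in control and with oxythiamine, which share no library, had a Pearson's r of 0.636 and a Spearman's rho of 0.657. With total-count scaling the counts were 1599 and 445 in the control and 2513 and 369 with oxythiamine.

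Neighbouring genes often lay apart in the same direction at 180 min. There were 29 runs of 4 or more consecutive measured genes at least 2-fold higher, holding 188 genes, and 45 runs at least 2-fold lower, holding 272 genes, where shuffling the ratios among genes gave means of 1.62 and 1.63 runs. The longest run of higher genes had 25 members, from PA2130 to PA2172, and included the catalase gene katE and the glycogen metabolism genes glgP and glgB. The longest run of lower genes had 23 members and was the ribosomal protein cluster from PA4241 to PA4263. The longest run of lower genes had 10 members with total-count scaling, and the longest run of higher genes had 7 with a mean of at least 100 reads. Further runs of lower genes held flgB to flgL, the glucose uptake genes around oprB, and soxB, soxD, soxA and soxG. Further runs of higher genes held the pel, pch and cyo clusters. At 30 min there was 1 run, of 5 lower genes, from liuD to liuR, and none in the shuffled ratios.

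One test was possible over both times, a model with time and treatment in which the spread of a gene is how far its treatment ratio differs between the times, with 1 residual degree of freedom. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes, with a smallest adjusted p of 0.948 and 98 genes, 1.86%, below an unadjusted p of 0.05. Within the gene lists 0 genes were called adjusted over the list alone, with the smallest adjusted p, 0.0815, among the enzymes using thiamine pyrophosphate. DESeq2 with the same model left 231 genes below an unadjusted p of 0.05 and called 3 genes higher, aceE (adjusted p = 0.000635), aceF (adjusted p = 0.000777) and PA2146 (adjusted p = 0.000783), and 2 lower, PA1420 and PA5391 (adjusted p = 0.0405 for both). For aceE, aceF and PA2146 the DESeq2 log2 ratios were 2.83, 2.83 and 5.34, and for PA1420 and PA5391 they were -3.24 and -3.16, each in the same direction at both times. The sizes differed between 30 and 180 min for PA2146 (1.34 and 5.04), PA1420 (-1.46 and -4.13) and PA5391 (-1.22 and -4.40). The DESeq2 value of PA2146 exceeded both of its ratios. At 30 min the ratio of PA2146 rested on few reads, so its direction there is uncertain. The authors' deposited table has 1 column of edgeR p-values whose comparison is not named. 310 genes there were below 0.05. The ranks of that column matched those of an exact test of the 2 libraries at 180 min, with a Spearman's rho of 0.9997. Such p-values set 1 library against 1 and leave out the variation between cultures. All of these genes measured here with enough reads, aceE and aceF among them, were at least 2-fold apart at 180 min. This follows from the use of the same 2 libraries and is no separate evidence.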

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

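Tests of the neighbouring genes, of counting error at 180 min and of a lag over all genes were laid down before their results were seen, and the tests of counting error, scaling and the other thiamine pyrophosphate enzymes for aceE and aceF, of depth at 180 min, and of a lag in each direction, were chosen afterwards.

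The ratios of aceE and aceF stood out at both times. Counting error is argued against, since the lowest end of their 4 counting intervals was 5.51-fold, and so is the scaling, since their lowest log2 ratio under 4 scalings was 2.37. A change of the whole chromosomal region, as from genomic DNA or copy number, is argued against by the 6 nearest measured genes, whose median log2 ratio was -0.000221 at 30 min and -0.43 at 180 min. A 2-fold or larger rise shared by the 19 other enzymes and partners in the thiamine pyrophosphate list is argued against at 30 min. Their median there was 0.19 with an upper bootstrap bound of 0.27. That bootstrap treats genes of one operon as independent, but the largest single ratio among the 19 was 0.53. A small shared rise is not argued against, since the median of all 21 members, 0.20, lay above the random range, which ended at 0.11. At 180 min 10 of the 19 were at least 2-fold higher. A response of aceE and aceF to oxythiamine is a hypothesis drawn from the same libraries and not tested, since the variation between cultures was not measured, and replicate cultures with oxythiamine, with and without added thiamine, would test it.

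The number of genes at least 2-fold apart was 1451 at 180 min against 65 at 30 min. Sequencing depth is argued against, since libraries thinned to the smallest total gave 1289 and 109 genes, a ratio of 11.8, and counting error alone gave 0.240% of the number at 180 min. A lag that keeps each gene between its control levels at 30 and 180 min is argued against as the whole explanation. For 55.3% of the genes, 803 of 1451, the treated level lay at least 2-fold outside that range, while 22.7% lay within it. Other scalings and thinning put 51.2% to 67.0% outside. Of the 803 genes, 527 lay beyond the control level at 180 min and 276 beyond that at 30 min. The 527 pass the 2-fold margin by their selection as 2-fold apart at 180 min. For them only the side on which they lie is informative. The control was not sampled between the 2 times, so a lag through levels that it passed in between cannot be judged from these values. The directions differed, with 68.8% of the 727 higher genes outside and 9.35% between, but 41.9% of the 724 lower genes outside and 36.0% between. A lag that keeps genes between the sampled control levels is thus argued against for the higher genes. For the lower genes it cannot be the whole explanation, since 303 of the 724 lay at least 2-fold outside. It stays open for the 261 lower genes between the levels. The split by direction was made with the main scaling only. An effect of longer exposure and a difference between the single cultures at 180 min are both left untested, and replicate cultures sampled at both times would be needed to tell them apart.

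Of the 19 genes at least 2-fold apart in opposite directions at the 2 times, 3 belong to the genes named by the rule fixed beforehand, and 4 of the 26 lists stood apart in opposite directions. With a mean of at least 100 reads 1 gene was higher at 30 and lower at 180 min and 5 the other way, instead of 5 and 14. The difference between the times was not tested for any of these. The median log2 ratio of the glucose catabolism list was 0.09 at 30 min and -1.15 at 180 min, a difference of -1.24. That of the quorum sensing list was 0.27 and -0.42, a difference of -0.69. That of the type III secretion list was -0.22 and 0.68, a difference of 0.90. That of the heat shock list was 0.21 and -1.15, a difference of -1.36. exaB had log2 ratios of 1.16 and -2.18, a difference of -3.34, with 2 and 8 reads at 30 min and a log2 ratio there of 0.80 with a prior count of 5. oprN had -1.30 and 1.24, a difference of 2.54, and 0.84 at 180 min in thinned libraries. cioB had -1.19 and 1.47, a difference of 2.65.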

How the results depend on the processing

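Settings were changed one at a time, and the libraries thinned to the smallest total were added after seeing the data. No list median that stood apart and no named gene at least 2-fold apart changed its direction under the settings run for it. The function categories were run under the main setting only. The number of genes higher at 30 min was 25, and became 13 with a prior count of 5, 43 with no filter, 6 with a mean of at least 100 reads and 48 in thinned libraries, while the 40 lower genes became 20 and 61 in the last 2 of these. Total-count scaling moved the counts at 180 min to 1159 higher and 473 lower, those of the difference between times to 301 and 135, those of time in the control to 1599 and 445, those of time with oxythiamine to 2513 and 369, and the runs of higher genes to 63. With a mean of at least 100 reads, which leaves 3579 genes, 318 genes were higher and 503 lower at 180 min. Higher genes were then 38.7% of those apart, against 50.1% in the main setting. This filter also gave 90 genes with a higher ratio at 180 than at 30 min, 708 higher with time under oxythiamine, 3 higher and 5 lower at both times, and 9 runs of higher genes. Genes higher at 30 and lower at 180 min were 3 with total-count scaling or a prior count of 5, 1 with a mean of at least 100 reads and 11 in thinned libraries, and genes lower at 30 and higher at 180 min were 8 with a prior count of 5, 22 with no filter and 5 with a mean of at least 100 reads. Genes higher at both times were 7 with a prior count of 5 and 24 with no filter, and thinned libraries gave 19 runs of higher genes. DESeq2 called 3 genes higher and 2 lower where edgeR called 0. Beyond what a setting's own construction shows, the cause was not tested. Of the counts and the correlation run under these settings 135 values stayed within their limits and 33 moved. Of the list medians and named genes 2129 stayed, 186 moved by more than their interval, 6 list medians newly stood apart and 2 no longer did. Of the 186, 76 were named genes under total-count scaling. With other scaling or filters the edgeR model also called 0 genes, with 147 below an unadjusted p of 0.05 for median-of-ratios scaling, 175 for no filter and 28 without the time term. Keeping ribosomal and transfer RNA rows could not be run because the table has none, and the pseudocounts planned for normalized values did not apply to counts. The time term of the model sets treated against control within each time. No further pairing was possible, because each group had 1 library and so no replicate number to serve as a block, and for the same reason no library could be left out. With a mean of at least 100 reads 5 of 12 heat shock and 1 of 9 ATP synthase genes were lower at 180 min, and thinned libraries had 4 of 20 type III secretion and 4 of 7 alginate genes higher. As a limit of depth, counting error alone made a mean of 29.5 genes at least 2-fold apart at 30 min and 3.48 at 180 min.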

Other observations

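The runs and genes in this paragraph were chosen after their values at 180 min were seen. The run PA1316 to PA1324, which holds the cytochrome bo oxidase genes cyoA to cyoE, had a median log2 ratio of 2.53 with oxythiamine, and the run of ccoP2, ccoQ2, ccoO2 and ccoN2, for a cbb-type oxidase, had a median of -2.48. cioA and cioB, for the cyanide-insensitive oxidase, had ratios of 2.42 and 1.47 at 180 min after -1.13 and -1.19 at 30 min. A run of 13 genes from algL to PA3559, which joins the end of the alginate cluster to the lipid A modification genes arnB to arnF, had a median of 1.60. Runs of higher genes also held aruC to aruE, for arginine breakdown, with a median of 1.83, glpF, glpK, glpR and glpD, for glycerol use, with 1.68, and maiA, fahA and hmgA, for tyrosine breakdown, with 1.66. Runs of lower genes held 11 genes of the type VI secretion cluster around hcp1 and clpV1, with a median of -1.84, rpoC to secE with -1.90, 7 genes from PA1415 to gbuA with -3.98, PA4907 to PA4914 with -3.06, and cobD to PA1280, with 5 cobalamin synthesis genes, with -1.29.

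Among the eggNOG function categories of the deposited table, translation had a median log2 ratio of -0.56 at 180 min, with 62 of 188 genes at least 2-fold lower and 5 higher, below all random lists of its size and expression. Cell motility had a median of -0.55, with 25 of 104 lower and 7 higher, and lipid metabolism had -0.17, with 46 of 228 lower and 29 higher, and both stood below the random lists, although the shift of total-count scaling would carry the lipid median above 0. Carbohydrate metabolism had a median of 0.23, with 57 of 206 genes higher and 25 lower, and inorganic ion transport 0.26, with 75 of 312 higher and 37 lower, and neither stood apart. At 30 min energy production had a median of 0.05, above 99.4% of random lists, with 5 of 334 genes at least 2-fold higher and 3 lower, and motility and nucleotide metabolism stood below with medians of -0.05 and -0.03. The other categories were within the random range at both times.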
